A study of Mus musculus with 8 samples.

How the data were processed

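RNA was measured in 8 libraries of sorted mouse CD4 T cells, 2 from each of 4 populations: naive and effector Tconv and resting and activated Treg. Per the labels' protocols, cells were taken from male Foxp3-GFP mice aged 8 to 10 weeks, RNA was extracted with TRIzol, and libraries were made from total RNA with a stranded kit. Reads were processed with STAR and RSEM on the build mm10, per the submitters' processing notes. Versions, the annotation and the strand setting are not given in the sources used here. The values that the authors deposited are expected counts per gene, which RSEM estimates by dividing reads that fit several genes, so they need not be whole. Between 6.96% and 7.74% of genes per library had counts more than 0.005 from a whole number, and 3791 of the tested genes did so in at least 1 library. Members of near-identical families and overlapping genes are therefore uncertain.

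Expected counts were rounded to whole numbers. The 92 spike-in entries held 0 counts in all libraries and were left out, which left 55573 genes. Gene classes were those deposited with the counts. Coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10, matched by gene ID for 55180 genes (99.3%). Totals ran from 20461955 to 26839602 counts per library, and 18853 to 21396 genes had at least 1 count. Mitochondrial ribosomal RNA took 18.6% to 29.7% of the counts, the small noncoding RNAs 7SL 7.10% to 9.48% and 7SK 3.86% to 5.10%, and protein-coding genes 46.4% to 61.2%, so the depth left for messenger RNA differed between libraries. CPM values use library sizes scaled by TMM, whose factors ran from 0.792 in resting Treg library 1 to 1.07.

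Differences were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, quasi-likelihood F-test, two-sided) in 1 model of all 8 libraries with a mean per group, because groups of 2 give few degrees of freedom alone. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15563. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 5 comparisons: effector against naive Tconv, activated against resting Treg, resting Treg against naive Tconv, activated Treg against effector Tconv, and the difference between Treg and Tconv in the change with activation. Standard errors are those of the log2 fold change. A fold against a group with no counts was computed against 3 counts over the group and is given as a lower bound. With 1 to 3 counts in a group, the ratio of CPM values is given with its exact 95% interval. Intervals and floors cover counting error only. With 2 libraries per group, no sample can be tested as an outlier, and regroupings of the samples are too few to be informative.

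Gene lists were fixed before the data were examined, as were the comparisons, the tests, the named-gene rule and the alternatives except where stated. They held 334 genes in 21 lists, of which 333 were in the table and 322 were tested. Programs covered the Treg signature, naive and quiescence genes, effector Treg, helper effector, follicular helper, inhibitory receptor and anergy, TCR-induced early genes, TET and DNA methylation, ascorbate uptake and recycling, cell cycle, glycolysis, cholesterol synthesis, homing receptors, cytokine receptors and interferon-stimulated genes. There were 5 lists of other cells that a CD4 gate could hold (NKT and innate-like T, B cell, myeloid, CD8 T, erythroid and platelet), and 1 of stress and sort handling. Foxp3 and Cd44 were in no list. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 21 lists. Calls of members are counted over all genes and adjusted over the list alone. With a correlation estimated from the data 41 of 58 list calls did not hold, and the adjusted p is then given beside the call. The TET and DNA methylation list had a median and a camera direction of opposite sign in all 5 comparisons, and its camera test did not pass in any of them.

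Named genes followed a fixed rule. Part 1 took the 10 largest positive and negative log2 fold changes among called genes with a mean of at least 10 CPM in the higher group and both libraries of one group above both of the other, or 8 each way for the difference. Gene models without an approved name, pseudogenes and antigen receptor V, D and J segments were left out. The other parts took up to 4 members of each list with the smallest p and any member against its list's direction, Foxp3, Cd44 and Cd4 in every group, and Tet1, Tet2, Tet3 and the Slc23a1 to Slc23a3 transporters in every comparison because of the series title. Further list members are named without values where they are exceptions to a count, and values of some genes that the rule takes are not given here.

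Alternatives were RLE size factors, DESeq2 1.42.0 with its Wald test, limma-voom, no filter beyond a total above 0, a filter of at least 1 CPM in at least 2 libraries, the replicate number as a block, each library left out, and only the 4 libraries compared. For lists they were an estimated correlation, fry, a prior count of 0.5, the block and each library left out, and for correlations only genes called in either comparison. A run on protein-coding genes only was added after seeing the data, because of the noncoding share of resting Treg library 1. The spread against which a change of these correlations was judged, the SD over the values with 1 library left out, was also chosen then.

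The test was checked on simulated counts drawn from the real means and library sizes with 200 changed genes, 67 by 1.5-fold, 67 by 2-fold and 66 by 4-fold. These were drawn from genes with a mean above 1 CPM, and no other gene differed between groups. The shares below hold for that setting and are not the power of the reported comparisons, where many more genes passed. Of those changed 2-fold it recovered 77.6% for effector against naive Tconv (15036 genes), 79.1% for activated against resting Treg (15073), 71.6% for resting Treg against naive Tconv (15102), 85.1% for activated Treg against effector Tconv (15037) and 53.7% for the difference (15055). At 1.5-fold these shares were 40.3%, 41.8%, 44.8%, 44.8% and 11.9%. False calls made up 8.44%, 12.0%, 4.08%, 6.75% and 8.11% of the calls in the same order, above the nominal 5% in 4 of 5. The limit on this share at which the check stops was raised from 12% to 15% after a first run had stopped there. For the closing part, lists of plasmacytoid dendritic (first and second), conventional dendritic and plasma cell genes were written, and histone and ribosomal protein genes and genes of oxidative phosphorylation encoded in mitochondria and nucleus were summarised.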

Results

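Total RNA was sequenced from 4 populations of CD4 T cells that had been sorted by flow cytometry from spleen and peripheral lymph nodes of male mice aged 8 to 10 weeks. The mice carried a GFP reporter of Foxp3, the transcription factor that defines the regulatory T (Treg) cell lineage. Conventional T (Tconv) cells lacked the reporter and were divided by surface markers into a CD44-negative naive population and a CD44-positive effector population. Treg cells carried the reporter and were divided into resting cells with low CD44 and activated cells with high CD44. Each of the 4 groups held 2 libraries, and total expected counts ran from 20461955 to 26839602 per library. At that depth 3 counts in a library corresponded to 0.108 to 0.150 CPM, the counts scaled to library size. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical. Across genes, which are not independent replicates, the log2 CPM of the 2 libraries of a group correlated at r = 0.991 in naive Tconv, 0.989 in effector Tconv, 0.987 in resting Treg and 0.986 in activated Treg. Taken over all genes, no pair of libraries matched within counting noise, since chi-square per gene was 16.5, 124, 123 and 25.2 in the same order. This is a mean against totals without TMM scaling, which abundant noncoding RNAs can dominate, so it does not measure the scatter of a typical gene.

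The genes behind the sort were read first in every group. Foxp3 (ENSMUSG00000039521.13, GRCm38 chromosome X, 7573644 to 7595245) stood at 102 ± 10.9 CPM (SD, n = 2) in resting Treg and 108 ± 3.67 CPM in activated Treg, against 0.689 ± 0.06 CPM in naive and 0.698 ± 0.299 CPM in effector Tconv. Its counts overlap those of the neighbouring transcript Flicr and were not whole in 7 libraries. Cd44 (ENSMUSG00000005087.17, chromosome 2, 102811141 to 102901665), which encodes the hyaluronan receptor used as the activation marker, was at 14.4 ± 2.31 CPM in naive and 192 ± 1.27 CPM in effector Tconv. In Treg it was at 29.4 ± 7.68 CPM in resting and 133 ± 9.94 CPM in activated Treg (SD, n = 2 each). Cd4 (chromosome 6, 124864692 to 124888221) lay at 503 ± 24.5 CPM in naive Tconv, 448 ± 41.7 CPM in effector Tconv, 328 ± 27 CPM in resting Treg and 405 ± 19.3 CPM in activated Treg. It was 1.53-fold lower in resting Treg than in naive Tconv by edgeR (adjusted p = 0.00353), a call lost without naive Tconv library 2 (adjusted p = 0.0536).

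The first principal component of log2 CPM held 63.5% of the variance and separated the CD44-high from the CD44-low populations, and the second held 20.9% and separated Treg from Tconv. Replicates lay beside each other, at -102 and -102 on the first component for naive Tconv and 80.8 and 74.5 for effector Tconv. Resting Treg lay at -37.4 and -31.4, and activated Treg at 58.5 and 59.2. Resting Treg library 1 stood apart in composition: mitochondrial ribosomal RNA took 29.7% of its counts and protein-coding genes 46.4%, against at most 22.9% and at least 53.6% in the other 7 libraries. Its 10 most abundant genes held 47.8% of its counts.

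**Figure D1:**
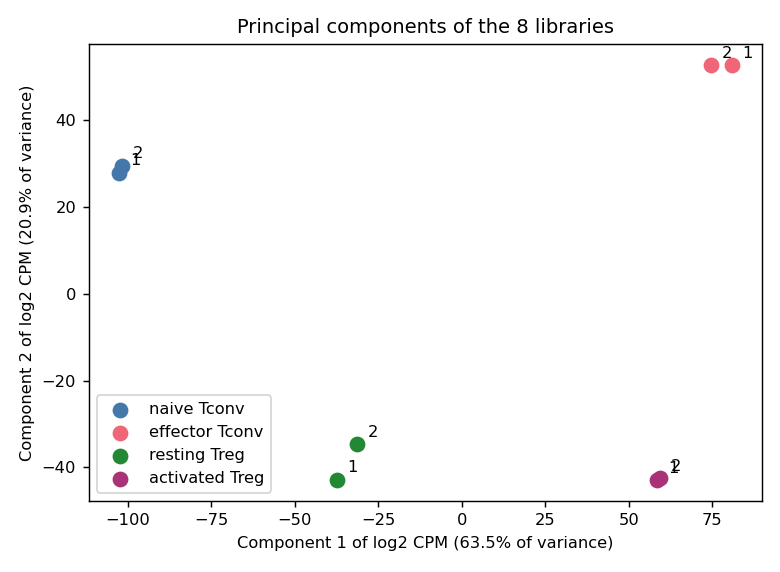
Principal components 1 and 2 of log2 CPM for the 8 libraries, with 1 point per library coloured by sorted population; axes give the component scores and the percent of variance. Both CD44-high populations lie at positive values of component 1, and both Treg populations at negative values of component 2.

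Because the series concerns ascorbate and TET activity, the genes of the TET dioxygenases, which oxidise 5-methylcytosine in DNA and use ascorbate as a cofactor, were compared in all groups. Tet1 (ENSMUSG00000047146.17, chromosome 10, 62804570 to 62908996) was highest in naive Tconv at 43.9 ± 2.31 CPM (SD, n = 2), and lay at 18.4 ± 1.14 CPM in effector Tconv, 19.1 ± 0.251 CPM in resting Treg and 14.7 ± 0.477 CPM in activated Treg. It was 2.38-fold lower in effector than in naive Tconv (log2 fold change -1.25 ± 0.087 SE, edgeR adjusted p = 4.85e-06) and 2.3-fold lower in resting Treg than in naive Tconv (-1.20 ± 0.087, adjusted p = 1.6e-05). Tet3 (ENSMUSG00000034832.15, chromosome 6, 83362373 to 83459084) fell from 165 ± 6.04 CPM in naive to 98.7 ± 4.11 CPM in effector Tconv (log2 fold change -0.74 ± 0.12, adjusted p = 0.00134). The Tet1 difference between Treg and Tconv in the change with activation was 0.87 ± 0.12 on the log2 scale (adjusted p = 0.0023). For Tet2 that difference was -0.12 (adjusted p = 0.705), and for Tet3 0.18 (adjusted p = 0.662).

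Tet2 (ENSMUSG00000040943.12, chromosome 3, 133463679 to 133545139) was at 79.3 ± 1.56 CPM (SD, n = 2) in naive Tconv, 99 ± 11.6 CPM in effector Tconv, 88.9 ± 1.72 CPM in resting Treg and 102 ± 4.31 CPM in activated Treg. Its rise in effector against naive Tconv was small (log2 fold change 0.32 ± 0.092, edgeR adjusted p = 0.0211). The adjusted p was 0.0882 without naive library 1, 0.116 without naive library 2 and 0.168 without effector library 1. Tet3 fell from 142 ± 28.3 CPM in resting to 96.8 ± 3.17 CPM in activated Treg (-0.56 ± 0.12, adjusted p = 0.00975), with an adjusted p of 0.0643 without activated library 1. In resting Treg against naive Tconv, where the difference was -0.21 (adjusted p = 0.29), Tet3 stood at -0.43 (adjusted p = 0.00913) without resting library 2. Tet1 also fell slightly in activated against resting Treg (log2 fold change -0.38 ± 0.091, adjusted p = 0.0135), with adjusted p of 0.0541 and 0.102 without activated library 1 or 2. In activated Treg against effector Tconv, Tet1 had a log2 fold change of -0.33 ± 0.091 (adjusted p = 0.0313). Of the 8 omissions 6 ended this call, with adjusted p of 0.0577 and 0.0574 without naive library 1 or 2, 0.192 and 0.0579 without effector library 1 or 2, and 0.109 and 0.184 without activated library 1 or 2.

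Slc23a2 (ENSMUSG00000027340.15, chromosome 2, 132052496 to 132145108), which encodes a sodium-dependent ascorbate transporter, was at 37.2 ± 0.666 CPM (SD, n = 2) in naive and 36.5 ± 0.61 CPM in effector Tconv. In Treg it was at 45.8 ± 0.494 CPM in resting and 46.2 ± 0.741 CPM in activated Treg. It was higher in both Treg populations than in their Tconv counterparts, by 0.30 ± 0.069 on the log2 scale in resting Treg (edgeR adjusted p = 0.0151) and 0.34 ± 0.069 in activated Treg (adjusted p = 0.00668). With activation it did not pass the test in Tconv (-0.028, adjusted p = 0.79) or in Treg (0.013, adjusted p = 0.917). The lineage calls were lost without naive library 1 or 2 for resting Treg (adjusted p = 0.0853 and 0.0895), and without effector library 1 or activated library 2 for activated Treg (0.0562 and 0.0639). The related transporter genes Slc23a1, with 4 counts over the 8 libraries, and Slc23a3, with 27, were too low to test.

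**Figure D2:**
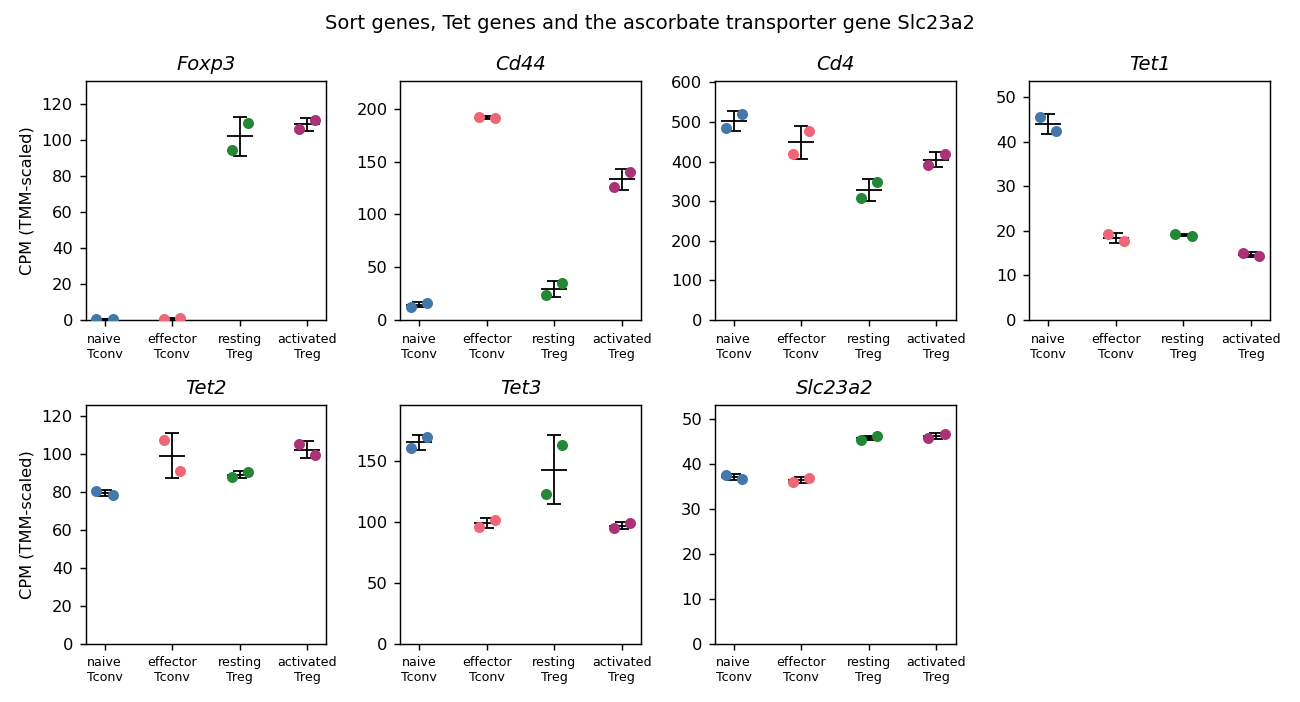
Abundance in CPM of the sort genes Foxp3, Cd44 and Cd4 and of Tet1, Tet2, Tet3 and Slc23a2 in the 4 populations; points are libraries, and bars with error bars are the mean ± SD of n = 2 libraries. Tet1 is highest in naive Tconv, and Slc23a2 is higher in both Treg populations than in both Tconv populations.

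Effector against naive Tconv addressed what separates antigen-experienced from naive conventional cells. Effector genes rose in effector Tconv, and several of them are also expressed by innate-like T cells, whose markers rose in the same libraries. Il18rap, a subunit of the interleukin 18 receptor, went from 0.471 ± 0.174 to 116 ± 5.14 CPM (SD, n = 2 each), 242-fold higher (log2 fold change 7.92 ± 0.16 SE, edgeR adjusted p = 1.54e-08). Nkg7, which encodes a cytotoxic granule protein, was 274-fold higher (0.191 ± 0.0114 against 53.8 ± 1.02 CPM). Id2, an inhibitor of E protein transcription factors, was 18.5-fold higher (24.3 ± 0.84 against 449 ± 20.6 CPM). Ifng, the gene of interferon gamma, had no counts in either naive library and 22.3 ± 1.49 CPM in effector Tconv, at least 311-fold higher when naive cells are set at 3 counts over the group. Genes of naive cells fell: Igfbp4 (ENSMUSG00000017493.12, chromosome 11, 99041244 to 99054392), which encodes an insulin-like growth factor binding protein, dropped from 409.6 ± 11.4 to 12.7 ± 0.488 CPM, 32.3-fold lower (-5.01 ± 0.23, adjusted p = 3.92e-07). The lymph node homing receptor Ccr7 was 5.56-fold lower (322 ± 11.2 against 57.9 ± 4.3 CPM, adjusted p = 2.07e-07). S1pr1, a receptor for egress from lymph nodes, was 3.6-fold lower (628 ± 5.73 against 174 ± 24.7 CPM, adjusted p = 3.61e-06).

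Of the 25 tested helper effector genes, 24 rose and 1, Cd40lg, did not pass the test (24 higher adjusted over the list alone; camera adjusted p = 9.65e-16). All but 1 of the 26 effector Treg genes, Areg, also rose in these Foxp3-negative cells (25 higher, 26 adjusted over the list alone; camera adjusted p = 9.65e-16). Among them Irf4, a transcription factor of activated lymphocytes, was at 10.5 ± 0.156 against 80.5 ± 2.83 CPM (SD, n = 2 each). Follicular helper genes rose in 12 of 13 cases (12 adjusted over the list alone; camera adjusted p = 7.74e-08). The B cell follicle homing receptor Cxcr5 was at 2.35 ± 0.365 against 82.2 ± 1.32 CPM, and Maf, a transcription factor of follicular and interleukin 10 producing T cells, at 4.34 ± 0.718 against 230.3 ± 13.7 CPM. The Treg signature list rose in 21 of 24 members, and Ikzf4, Ecm1 and Gpr83 fell (21 and 3 adjusted over the list alone; camera adjusted p = 1.73e-09). Ikzf2, the gene of the transcription factor Helios, reached 213 ± 19.9 CPM in effector Tconv against 5.61 ± 0.272 CPM in naive cells, while Foxp3 did not pass the test (log2 fold change -0.007 ± 0.34, adjusted p = 0.99). Inhibitory receptor and anergy genes rose in 13 of 20 cases and 3, Cd5, Dgka and Tox, fell (14 and 3 adjusted over the list alone; camera adjusted p = 5.34e-05). Pdcd1, the gene of the inhibitory receptor PD-1, went from 2.6 ± 0.653 to 40 ± 0.0434 CPM. Among the genes that fell, the edgeR calls were lost with single libraries left out for Cd5 (adjusted p up to 0.238 without naive 1, naive 2 or effector 1) and Tox (adjusted p up to 0.198 without naive 1, naive 2, effector 1, effector 2, activated 1 or activated 2).

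Naive and quiescence genes fell in 18 of 20 cases and rose in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 3.56e-11, or 0.138 with an estimated correlation). Ccr9, a gut homing receptor also expressed by plasmacytoid dendritic cells, rose against that direction, from 7.69 ± 1.64 to 132 ± 2.11 CPM (SD, n = 2 each), and Il7r did not pass the test. Cell cycle genes rose in 22 of 24 cases (22 adjusted over the list alone; camera adjusted p = 2.53e-10), with the proliferation marker Mki67 20.5-fold higher. Homing receptors rose in 16 and fell in 4 of 23 cases (16 and 4 adjusted over the list alone; camera adjusted p = 5.45e-05, or 0.138 with an estimated correlation). Those that fell were Ccr7, S1pr1, S1pr4 and Gpr183. Genes of ascorbate uptake and recycling rose in 7 of 9 cases (7 adjusted over the list alone; camera adjusted p = 0.00465, or 0.165 with an estimated correlation). Among these, Glrx, a glutaredoxin, was 4.02-fold higher (9.69 ± 0.769 against 39 ± 0.363 CPM) and Slc2a3, a transporter of glucose and dehydroascorbate, 2.48-fold higher (37.8 ± 1.39 against 93.5 ± 2.99 CPM). The TET and DNA methylation list did not pass camera (4 higher, 4 lower, the same numbers adjusted over the list alone, camera adjusted p = 0.81), while fry, which asks whether members change at all rather than more than other genes, placed it higher (adjusted p = 0.0156). Without naive library 1 or effector library 1, 2 of its genes were higher. Beside Tet1 and Tet3, Idh2, a mitochondrial isocitrate dehydrogenase, fell (log2 fold change -0.76 ± 0.076), and the TET regulator gene Cxxc5 rose from 0.788 ± 0.0807 to 10.2 ± 0.5 CPM.

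Genes named for other cell types also rose in effector Tconv. All 15 tested myeloid genes rose (15 adjusted over the list alone; camera adjusted p = 8.48e-09, or 0.0861 with an estimated correlation). They include Siglech, a lectin of plasmacytoid dendritic cells, at 0.0954 ± 0.00569 CPM (SD, n = 2) in naive and 96.3 ± 3.85 CPM in effector Tconv. B cell genes rose in 11 of 14 cases (11 adjusted over the list alone; camera adjusted p = 5.45e-05, or 0.165 with an estimated correlation), with Cd79b at 4.73 ± 1.22 CPM. NKT and innate-like genes rose in 10 of 11 cases (10 adjusted over the list alone; camera adjusted p = 7.74e-08), and the constant segment of the T cell receptor delta chain, Trdc, did not. Zbtb16 (chromosome 9, 48654297 to 48836222), which encodes the innate-like T cell factor PLZF, reached 67.6 ± 0.273 CPM in effector Tconv, and Klrb1c, an NK cell receptor gene, 134 ± 13.2 CPM. Their effector to naive count ratios were 2840.1 (95% counting interval 509 to 112211) and 5627 (95% counting interval 1009.6 to 222289), with 1 naive library at 0 for each. Klrc1, another NK cell receptor gene that shares reads with related genes, had no naive counts and was at least 523-fold higher. Cd8a rose and Cd8b1 fell among the 2 CD8 genes (camera adjusted p = 0.698; 1 and 1 adjusted over the list alone). Of 6 erythroid and platelet genes 5 rose and Itga2b fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.192). Left-out libraries ended the edgeR calls of Cd8b1 (adjusted p up to 0.305 without naive 1, effector 1, effector 2, activated 1 or activated 2) and Itga2b (adjusted p up to 0.198 without naive 1, naive 2, effector 1, effector 2, activated 1 or activated 2). They also ended those of Hba-a1 (adjusted p up to 0.146 without naive 2 or effector 1), Alas2 (adjusted p up to 0.128 without naive 1, naive 2 or effector 1) and Hbb-bs (adjusted p up to 0.196 without naive 2 or effector 1), which encode hemoglobin chains and a heme synthesis enzyme. The erythroid and platelet count of 5 fell to 1 without naive library 2 or effector library 1. Cd8a stood at 5.09 on the log2 scale, or 5.89 without naive library 2.

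In this comparison 6199 of 15563 tested genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 3709 higher and 2490 lower in effector Tconv. The lower count was 1572 without naive library 1, 1476 without naive library 2 and 1549 without effector library 1. At least 2-fold differences made up 2464 and 667 of these. The fitted values of Zbtb16 and Klrb1c rest on 1 naive count each: Zbtb16 stood at 13.63 on the log2 scale without naive library 1 and 10.27 without naive library 2, and Klrb1c at 14.62 and 11.26.

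Activated against resting Treg asked the same of Foxp3-positive cells. Klrg1 (ENSMUSG00000030114.8, chromosome 6, 122270596 to 122282882), an inhibitory lectin receptor of differentiated lymphocytes, rose from 0.485 ± 0.0216 CPM in resting to 65.4 ± 7.95 CPM in activated Treg (SD, n = 2 each), 134-fold (log2 fold change 7.06 ± 0.20 SE, edgeR adjusted p = 2.52e-07). Il10 (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974), the gene of the immunosuppressive cytokine interleukin 10, rose 81.9-fold, from 0.159 ± 0.0585 to 13.1 ± 1.19 CPM (6.36 ± 0.33, adjusted p = 3.09e-06). The calcium-binding protein gene S100a4 rose 31-fold (4.52 ± 0.687 to 139 ± 9.28 CPM). Itgae, the integrin chain CD103 that binds epithelial E-cadherin, rose 14.7-fold (10.6 ± 0.976 to 155 ± 31.8 CPM). Icos, a costimulatory receptor, rose 9.83-fold (38.8 ± 3.74 to 381 ± 33.8 CPM, adjusted p = 6.99e-07). Satb1, a chromatin organiser whose counts were partly shared in all 8 libraries, fell 4.34-fold (519 ± 39.9 to 119.5 ± 27 CPM, adjusted p = 1.71e-05). Igfbp4 fell 5.19-fold (126 ± 14.6 to 24.3 ± 8.79 CPM, adjusted p = 5.43e-05).

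All 26 tested effector Treg genes rose (26 adjusted over the list alone; camera adjusted p = 3.81e-21). Cell cycle genes rose in 22 of 24 cases (23 adjusted over the list alone; camera adjusted p = 1.74e-11), with Mki67 at 29.4 ± 2.08 against 195 ± 1.36 CPM (SD, n = 2 each). Naive and quiescence genes fell in 18 of 20 cases and rose in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 1.74e-11, or 0.127 with an estimated correlation). Ccr9 rose (log2 fold change 0.54), a call lost without activated library 1 (adjusted p = 0.0783). The Treg signature divided: 17 of 24 members rose and Il2ra, Ecm1, Gpr83 and Lrrc32 fell (18 and 4 adjusted over the list alone; camera adjusted p = 2.78e-05, or 0.0919 with an estimated correlation). Il2ra, the high-affinity interleukin 2 receptor chain, was at 348 ± 7.26 CPM in resting and 261 ± 16.2 CPM in activated Treg. Its call was lost without activated library 2 (adjusted p = 0.101), as was that of Lrrc32 (adjusted p up to 0.219 without naive 1, naive 2, effector 1, effector 2, resting 2, activated 1 or activated 2). Without activated library 2 the Treg signature had 2 lower genes. Foxp3 did not pass the test (log2 fold change 0.09 ± 0.11, adjusted p = 0.587). Helper effector genes rose in 21 of 25 cases (21 adjusted over the list alone; camera adjusted p = 6.94e-12), or in 13 without activated library 1. Follicular helper genes rose in 10 of 13 (11 adjusted over the list alone; camera adjusted p = 6.07e-07). Inhibitory receptor and anergy genes rose in 14 of 20 cases, with Dgka, a kinase that dampens antigen receptor signals, lower (16 and 2 adjusted over the list alone; camera adjusted p = 3.27e-06).

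Cholesterol synthesis genes fell in 6 of 19 cases and Pmvk rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0143, or 0.127 with an estimated correlation). Glycolysis genes rose in 9 of 16 cases and Eno1 fell (9 and 2 adjusted over the list alone), but the list missed the threshold (camera adjusted p = 0.0518), as it did in Tconv (8 higher and 1 lower, or 8 and 1 adjusted over the list alone; camera adjusted p = 0.0574). In the ascorbate list 4 of 9 genes rose and Gsto1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.119), with Glrx 7.75-fold higher at 79.1 ± 7.14 CPM (SD, n = 2) in activated Treg. TCR-induced early genes went both ways, with 8 higher and 4 lower of 24 (9 and 4 adjusted over the list alone; camera adjusted p = 0.167), as in Tconv (11 and 5, or 12 and 5 over the list alone; camera adjusted p = 0.217). Myc, a regulator of cell growth, was among those that fell in both. Myeloid genes rose in 14 of 15 cases (14 adjusted over the list alone; camera adjusted p = 4.99e-06, or 0.127 with an estimated correlation). Innate-like genes rose in 7 of 11, with Trdc lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00725, or 0.127 with an estimated correlation). Without activated library 1, 2 cholesterol genes were lower and 5 glycolysis genes higher, and without activated library 2, 2 cholesterol and 2 TCR-induced genes were lower. In Tconv 3 TCR-induced genes were lower without naive library 1, naive library 2 or effector library 1. Single left-out libraries ended the calls of Pmvk (adjusted p up to 0.0867 without resting 2 or activated 1), Eno1 (adjusted p 0.108 without activated 2), Gsto1 (adjusted p 0.144 without activated 2) and Trdc (adjusted p 0.0674 without activated 2). Of 14 B cell genes 6 rose (6 adjusted over the list alone; camera adjusted p = 0.0691). Ighm, the immunoglobulin mu heavy chain constant region, went from 170.5 ± 14.4 to 623 ± 47.9 CPM.

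For activation in Treg, 4181 genes passed the edgeR test, 2716 higher and 1465 lower in activated cells, of which 1592 and 375 differed at least 2-fold. The lower count was 885 without activated library 1. Without activated library 2 the number was 2414, 1801 higher and 613 lower, and activated Treg was then represented by 1 library.

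Resting Treg against naive Tconv compared the lineages among CD44-low cells. Il2ra (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193) was 330.4-fold higher in resting Treg, at 348 ± 7.26 against 1.06 ± 0.265 CPM (SD, n = 2 each; log2 fold change 8.37 ± 0.16 SE, edgeR adjusted p = 1.2e-08). Ikzf2 (ENSMUSG00000025997.13, chromosome 1, 69531214 to 69687245) was 127-fold higher at 714 ± 8.37 CPM (6.99 ± 0.13, adjusted p = 1.2e-08), and Ctla4, an inhibitory receptor that competes for costimulatory ligands, 34-fold higher at 155 ± 33.3 CPM (adjusted p = 2.33e-07). Lrrc32, which encodes a surface receptor for latent TGF-beta, had a count ratio of 2501 (95% counting interval 855 to 12129). Pde3b (ENSMUSG00000030671.9, chromosome 7, 114415281 to 114539251), a phosphodiesterase that degrades cyclic AMP, was 10.6-fold lower in resting Treg (192 ± 17.2 against 18.2 ± 1.05 CPM, -3.40 ± 0.11, adjusted p = 1.47e-07). Cd40lg, the helper ligand for B cells, was 5.4-fold lower (22.4 ± 0.283 against 4.13 ± 0.313 CPM), and the T cell factor gene Tcf7 2.63-fold lower (459.8 ± 20.1 against 175 ± 19.8 CPM, adjusted p = 1.9e-05).

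Of the 24 Treg signature genes 22 were higher in resting Treg, and Il10 and Tigit did not pass the test (23 higher adjusted over the list alone; camera adjusted p = 1.08e-26). Effector Treg genes were higher in 19 of 26 cases (22 adjusted over the list alone; camera adjusted p = 2.42e-14, or 0.0667 with an estimated correlation). TCR-induced early genes were higher in 11 of 24 cases, with Fosl2 lower (13 and 1 adjusted over the list alone; camera adjusted p = 0.000611, or 0.136 with an estimated correlation). Nr4a1, a nuclear receptor induced by antigen receptor signals, was at 42.8 ± 1.69 against 18.4 ± 2.11 CPM (SD, n = 2 each). Cholesterol synthesis genes were higher in 10 of 19 cases (13 adjusted over the list alone; camera adjusted p = 0.00107, or 0.102 with an estimated correlation). Naive and quiescence genes were lower in 10 of 20 cases with Ccr9 higher (10 and 1 adjusted over the list alone; camera adjusted p = 9.36e-06, or 0.24 with an estimated correlation). Inhibitory receptor and anergy genes were higher in 12 of 20 cases, with Dgka lower (14 and 1 adjusted over the list alone; camera adjusted p = 2.58e-07, or 0.0636 with an estimated correlation). In the ascorbate list Slc2a3 rose 2.47-fold and Gsto1, an omega glutathione transferase that reduces dehydroascorbate, 6.63-fold (3.53 ± 0.85 against 23.3 ± 0.702 CPM), and Slc23a2 was the third of 9 members to pass (3 adjusted over the list alone; camera adjusted p = 0.114). The cholesterol count was 5 without naive library 1 and 6 without naive library 2. The calls of Slc23a2 (adjusted p up to 0.0895 without naive 1 or naive 2) and Dgka (adjusted p up to 0.118 without naive 1 or naive 2) did not hold with single libraries left out.

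Interferon-stimulated genes were higher in 7 of 19 cases (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0305, or 0.492 with an estimated correlation). That call was lost without naive library 2 (0.183) or resting library 1 (0.233), the library with the high share of mitochondrial ribosomal RNA. B cell genes were higher in 11 of 14 cases with Ighm lower (12 and 1 adjusted over the list alone; camera adjusted p = 1.2e-05, or 0.152 with an estimated correlation). Myeloid genes were higher in 11 of 15 with Itgam lower (12 and 1 adjusted over the list alone; camera adjusted p = 2.29e-06, or 0.148 with an estimated correlation). Erythroid and platelet genes were higher in 5 of 6 cases (5 adjusted over the list alone; camera adjusted p = 0.00596, or 0.317 with an estimated correlation). The 2 lower calls were lost for Ighm (adjusted p up to 0.0958 without naive 1 or naive 2) and Itgam (adjusted p 0.0519 without naive 1), and the erythroid call for Alas2 (adjusted p up to 0.105 without naive 1, naive 2 or resting 1). Without naive library 1 the higher counts were 4 for interferon and 5 for B cell genes. Without naive library 2 they were 2 for interferon, 4 for B cell, 7 for myeloid and 3 for erythroid and platelet genes, and without resting library 2 they were 5 for B cell genes. In resting Treg the B cell receptor component Cd79b stood at 8.15 ± 0.443 CPM (SD, n = 2) and Ighm at 170.5 ± 14.4 CPM. In all, 3011 genes passed the edgeR test, 1879 higher and 1132 lower in resting Treg, with 1146 and 346 at least 2-fold. The number was 1730 without naive library 1 (1161 higher and 569 lower) and 1636 without naive library 2 (1178 and 458).

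Activated Treg against effector Tconv compared the lineages among CD44-high cells. Beside Foxp3 itself, Lrrc32 was 118-fold higher in activated Treg (138 ± 8.3 against 1.15 ± 0.0878 CPM, SD, n = 2 each; log2 fold change 6.89 ± 0.17 SE, edgeR adjusted p = 5.13e-08). Klrg1 was 44-fold higher (65.4 ± 7.95 against 1.49 ± 0.212 CPM, 5.46 ± 0.17, adjusted p = 1.51e-07). Il1rl1, the receptor for interleukin 33, was 20.1-fold higher (80.1 ± 6.61 against 4 ± 0.902 CPM), and Ctla4 10.1-fold higher (394 ± 16.4 against 38.9 ± 3.71 CPM). Neb, which encodes the muscle protein nebulin, was 56.9-fold higher at 206 ± 28 CPM (adjusted p = 5.13e-08). Lower in activated Treg were Zbtb16, 71.3-fold (0.952 ± 0.128 against 67.6 ± 0.273 CPM, -6.16 ± 0.15, adjusted p = 5.13e-08), and the chemokine receptor Cxcr6, 21.3-fold (22.5 ± 3.87 against 478 ± 12.3 CPM). Il21, a cytokine that helps B cells, was 21.4-fold lower (1.15 ± 0.359 against 24.3 ± 4.05 CPM). Fasl, the ligand of the death receptor Fas, was 9.25-fold lower and Id2 10.3-fold lower.

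All 24 Treg signature genes were higher in activated Treg (24 adjusted over the list alone; camera adjusted p = 8.59e-26). Effector Treg genes were higher in 19 of 26 cases, and Rora, Ccr2 and Cxcr3 were lower (20 and 3 adjusted over the list alone; camera adjusted p = 4.98e-10, or 0.0793 with an estimated correlation). Helper effector genes were lower in 20 of 25 cases, with the chemokine receptor Ccr6 and the homeodomain gene Hopx higher (20 and 2 adjusted over the list alone; camera adjusted p = 1.72e-11, or 0.0682 with an estimated correlation). Inhibitory receptor and anergy genes were higher in 13 of 20 cases, with Cd160 and Nrgn lower (13 and 2 adjusted over the list alone; camera adjusted p = 4.02e-05, or 0.0682 with an estimated correlation). TCR-induced early genes were higher in 12 of 24 cases, with Ier3 lower (13 and 2 adjusted over the list alone; camera adjusted p = 0.00153, or 0.127 with an estimated correlation). Of the 24 cell cycle genes 1, Mki67, passed over all genes (log2 fold change 0.34 ± 0.10, adjusted p = 0.0406; camera adjusted p = 0.508), and it did not pass when adjusted over the list alone. That call was lost without naive library 1 or 2 (0.0811 and 0.0854), effector library 2 (0.255), or activated library 1 or 2 (0.146 and 0.155). Cytokine receptors went both ways, with 11 of 23 higher and 7 lower (11 and 9 adjusted over the list alone; camera adjusted p = 0.544), as they did in effector against naive Tconv (12 and 8, or 12 and 8 over the list alone; camera adjusted p = 0.166). In the ascorbate list Glrx, Gsto1 and Slc23a2 were higher and Txnrd1 and Slc2a8 lower of 9 (the same numbers adjusted over the list alone; camera adjusted p = 0.544). Of 18 TET and DNA methylation genes 4, Tet1, Dnmt3b, Idh2 and Cxxc5, were lower (4 adjusted over the list alone; camera adjusted p = 0.651, and fry adjusted p = 0.0376), or 2 of these when any naive, effector or activated library was left out. With 1 library left out, calls were lost for Rora (adjusted p up to 0.061 without effector 1 or activated 1), Nrgn (adjusted p up to 0.127 without effector 2, activated 1 or activated 2), Ier3 (adjusted p up to 0.134 without effector 2 or activated 2) and Slc2a8 (adjusted p up to 0.172 without effector 2, activated 1 or activated 2). They were also lost for Slc23a2 (adjusted p up to 0.0639 without effector 1 or activated 2), Dnmt3b (adjusted p up to 0.203 without naive 1, naive 2, effector 1, effector 2, activated 1 or activated 2) and Tet1 (adjusted p up to 0.192 without naive 1, naive 2, effector 1, effector 2, activated 1 or activated 2).

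Innate-like genes were lower in activated Treg in 10 of 11 cases (10 adjusted over the list alone; camera adjusted p = 1.6e-10). Myeloid genes were lower in 8 of 15 cases, while the complement genes C1qa, C1qb and C1qc were higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.0205, or 0.578 with an estimated correlation). The list's call was lost without effector library 1 (0.111) or activated library 2 (0.0749), and C1qc lost its own without effector library 1 (edgeR adjusted p = 0.0546). Of the B cell genes, Ighm, Ighd and Cd79b were higher and Pax5, Cd22 and Blnk lower of 14 (the same numbers adjusted over the list alone; camera adjusted p = 0.89). Ighm was at 623 ± 47.9 CPM (SD, n = 2) in activated Treg against 215 ± 0.807 CPM in effector Tconv. Stress and sort handling genes, which mark damage during cell isolation, showed 2 higher and 3 lower of 11 (2 and 4 adjusted over the list alone; camera adjusted p = 0.721). In effector against naive Tconv they showed 3 and 1 (3 and 1 adjusted over the list alone; camera adjusted p = 0.258). In all, 3183 genes passed the edgeR test, 1563 higher and 1620 lower in activated Treg, with 756 and 965 at least 2-fold. The number was 2118 without effector library 1 (1017 higher), 2164 without effector library 2 (997 higher), 2059 without activated library 1 (1023 higher and 1036 lower) and 2119 without activated library 2 (1035 higher).

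**Figure D3:**
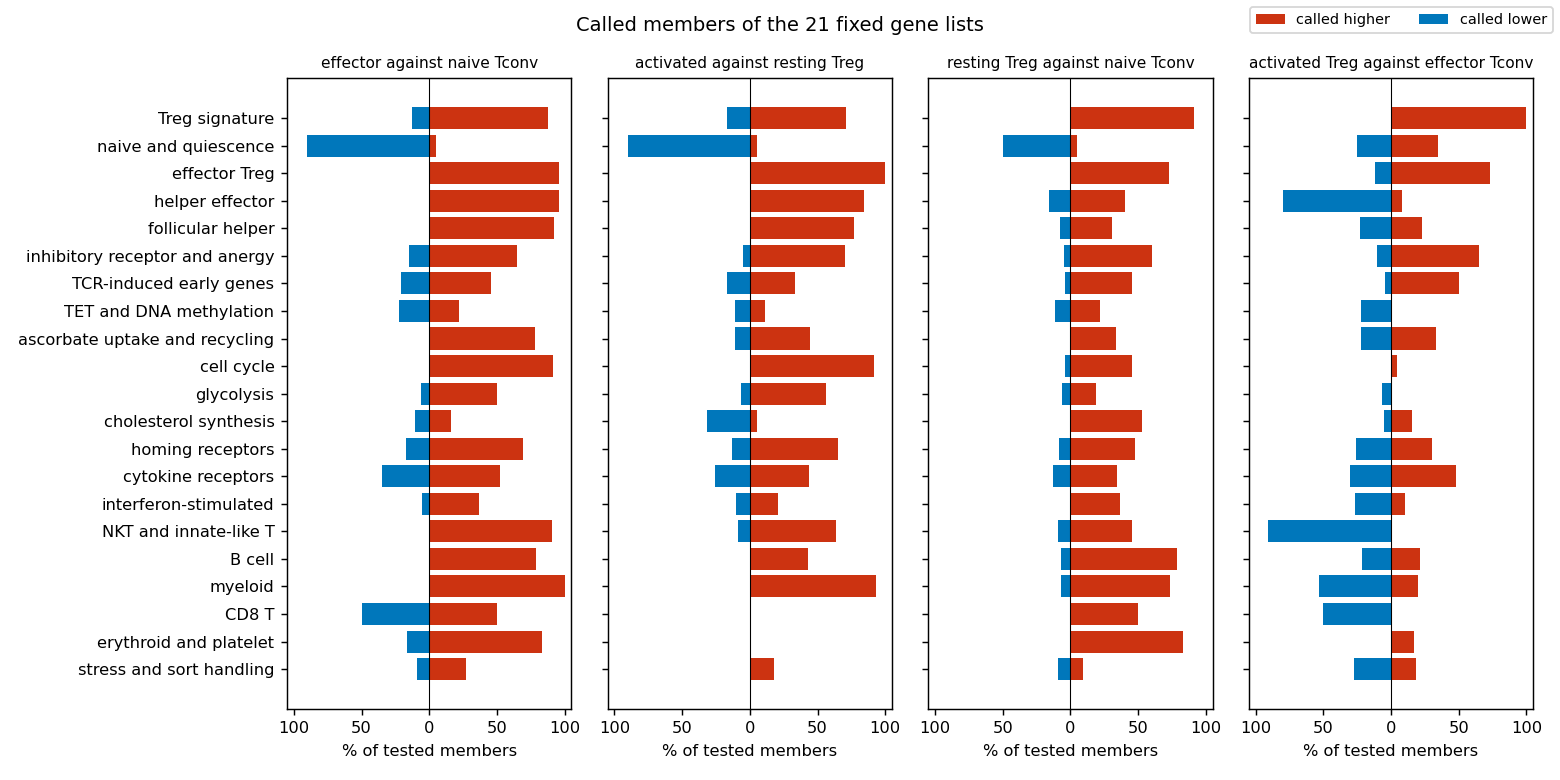
Percent of the tested members of each of the 21 gene lists called higher or lower in the 4 pairwise comparisons, by edgeR at an adjusted p under 0.05. The effector Treg list is higher throughout in activated against resting Treg, and the Treg signature list throughout in activated Treg against effector Tconv.

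The change with activation was then set against itself in the 2 lineages, as the difference between Treg and Tconv in log2 fold change. Il2rb, a member of the innate-like and cytokine receptor lists, and Ikzf2, a member of the Treg signature list, differed negatively. Il2rb, a shared receptor chain for interleukins 2 and 15, was at 13.3 ± 0.151 and 638 ± 70.5 CPM (SD, n = 2 each) in naive and effector Tconv. In resting and activated Treg it was at 589.8 ± 64.2 and 594 ± 40.7 CPM, a difference of -5.58 ± 0.18 (SE, edgeR adjusted p = 1.32e-06). For Ikzf2 the difference was -4.30 ± 0.15 (adjusted p = 1.52e-06). Nkg7 differed by -5.90 ± 0.30 (adjusted p = 8.44e-06) and Id2 by -2.26 ± 0.14, with larger rises in Tconv. The fall of Igfbp4 was smaller in Treg by 2.64 ± 0.29 (adjusted p = 0.000511), and so was that of Ccr7, by 1.53 ± 0.14 (adjusted p = 0.000166). Neb, at 9.87 ± 0.184, 3.61 ± 0.342, 70 ± 6.61 and 206 ± 28 CPM in naive Tconv, effector Tconv, resting Treg and activated Treg, differed by 3.004 ± 0.19 (adjusted p = 1.83e-05). Prdm1, a transcription factor of terminal differentiation, differed by 1.40 ± 0.25 (adjusted p = 0.0073).

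Helper effector genes differed negatively in 16 of 25 cases (21 adjusted over the list alone; camera adjusted p = 2.98e-19). Treg signature genes differed negatively in 15 of 24, with Ikzf4 and Ecm1 positive (16 and 2 adjusted over the list alone; camera adjusted p = 3.43e-07, or 0.0924 with an estimated correlation). Naive and quiescence genes differed in the positive direction in 10 of 20 cases, with Ccr9 negative (15 and 2 adjusted over the list alone; camera adjusted p = 1.64e-06, or 0.244 with an estimated correlation). Cell cycle genes differed negatively in 6 of 24 cases, with Stmn1 positive (9 and 1 adjusted over the list alone; camera adjusted p = 0.000207, or 0.184 with an estimated correlation). The negative cell cycle calls numbered 2 without naive library 2, effector library 1 or either activated library. Mki67 differed by -1.62 ± 0.16. In resting Treg against naive Tconv, 11 of the 24 cell cycle genes were higher and 1 lower (15 and 1 adjusted over the list alone). The camera adjusted p of the list there was 2.39e-05, or 0.144 with an estimated correlation. In activated Treg against effector Tconv 1 of 24 was called, so the negative difference alone does not show less cycling in activated Treg. Calls against their list's direction did not all hold with 1 library left out, as for Ikzf4 (adjusted p up to 0.0751 without naive 1, naive 2 or effector 2), Ecm1 (adjusted p up to 0.115 without naive 1, effector 1, effector 2 or activated 1) and Stmn1 (adjusted p up to 0.0543 without naive 1, naive 2 or activated 1). Among ascorbate genes Glrx was positive (0.95 ± 0.15) and Slc2a3 (-1.14 ± 0.11), Txnrd1 and Gsto1 negative of 9 (1 and 3 adjusted over the list alone; camera adjusted p = 0.187). Innate-like genes differed negatively in 8 of 11 cases (11 adjusted over the list alone; camera adjusted p = 4.84e-13). Myeloid genes did so in 10 of 15 (11 adjusted over the list alone; camera adjusted p = 2.65e-07, or 0.176 with an estimated correlation). The difference passed the edgeR test for 1513 genes, 408 positive and 1105 negative, of which 192 and 878 were at least 2-fold. The number was 982 without naive library 1 (217 positive), 994 without naive library 2 (194 positive) and 2274 with no filter on low counts (658 positive). The positive count was 249 without effector library 1, 246 without activated library 1 and 254 without activated library 2.

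Across the 15563 tested genes, log2 fold changes with activation in Tconv and in Treg correlated at Pearson r = 0.713 and Spearman rho = 0.699, with a slope of 0.395 for Treg on Tconv. Genes are not independent replicates, so no p-value was computed, and the comparisons have no library in common. Both comparisons called 2151 genes higher and 1027 lower, where independent lists would share 647 and 234. Opposite calls were made for 63 genes higher in effector Tconv and lower in activated Treg, and for 40 the other way. For lineage, log2 fold changes among CD44-low and CD44-high cells correlated at r = 0.212 and rho = 0.294, with 877 genes higher and 419 lower in Treg in both, where independent lists would share 189 and 118. Opposite calls numbered 248 for genes higher in resting Treg and lower in activated Treg, and 33 the other way. With no filter on low counts r fell to 0.411 for activation and 0.106 for lineage.

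**Figure D4:**
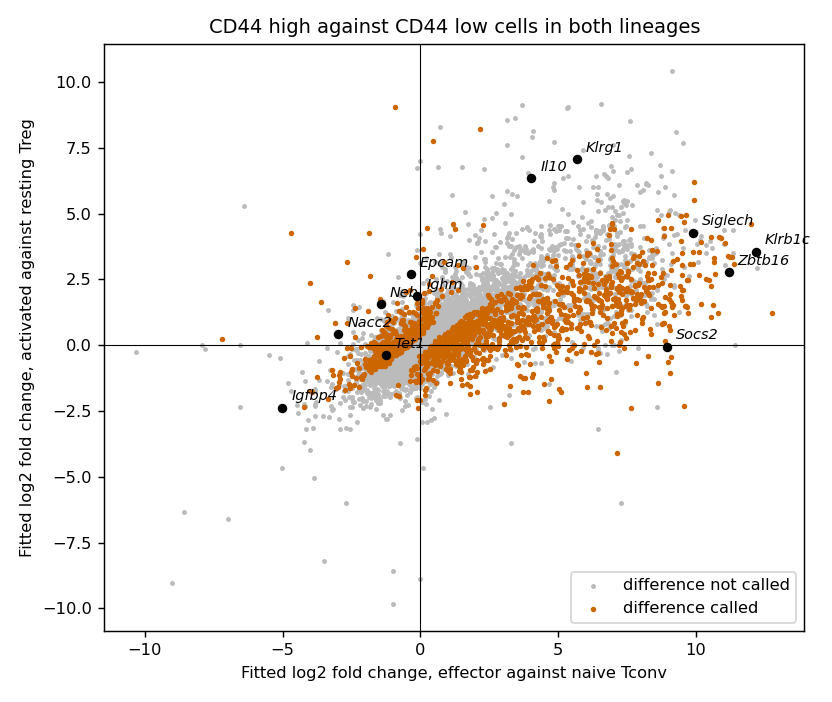
Fitted log2 fold change of effector against naive Tconv on the horizontal axis and of activated against resting Treg on the vertical axis, 1 point per tested gene, with the 1513 genes whose difference passed the edgeR test in orange. Most orange points lie below the line of equal change, 1105 of 1513.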

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

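Tests of the Treg and Tconv difference and of a second dendritic list, invariant NKT segments and shared Ighm reads were set before their results were seen, while those of other cell types alike, depth or scaling, B cells, plasma cells, gamma delta T cells and shared innate-like reads were chosen after. Of the latter, all but the B and plasma cell tests were recomputed with groups at 0 set to 3 counts once first values had been seen; the plasma cell and depth tests were replaced.

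The change with activation differed between Treg and Tconv for 1513 genes by edgeR, and the genes named for it stand out because the interaction itself passed the test. Positive differences on the log2 scale were 3.39 for Nacc2, 3.05 for Epcam, 3.004 for Neb, 2.955 for Cyp2s1, 2.69 for Rgmb, 2.64 for Igfbp4, 2.53 for Acvrl1 and 2.48 for Ncmap. Nacc2, a transcriptional repressor, was at 18.5 ± 0.208 CPM (SD, n = 2) in naive and 2.36 ± 0.0503 CPM in effector Tconv, and at 1.29 ± 0.0568 and 1.74 ± 0.23 CPM in resting and activated Treg. Epcam, an epithelial adhesion molecule, was at 1.81 ± 0.154 CPM in resting and 11.8 ± 1.33 CPM in activated Treg. Tet1 differed by 0.87 and Cd44 by -1.56.

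Negative differences were -11.56 for Klrc1, -10.09 for Tcrg-C2, -10.07 for Tcrg-C4, -10.05 for Tcrg-C1, -9.001 for Socs2, -8.61 for Klrb1c, -8.385 for Zbtb16 and -8.32 for Plekhf1. These fitted values involve libraries at or near 0 counts and are no bounds. Without naive library 1 or 2, Klrb1c stood at -11.06 and -7.73, Zbtb16 at -10.84 and -7.51, and Tcrg-C1 at -11.23 and -9.40, or -10.97 without activated library 1. Klrc1 lost its edgeR call without resting library 2 (adjusted p = 0.0527). Plekhf1 lost its call without naive library 1 or 2 (0.0701 and 0.0729), effector library 1 or 2 (0.0551 and 0.0585) or resting library 2 (0.234, at -7.00), and stood at -8.92 without resting library 1 and -8.99 without activated library 2. Socs2, a suppressor of cytokine signalling, was at 26.2 ± 0.773 CPM (SD, n = 2) in effector Tconv, 51.5 ± 6.37 CPM in resting and 49.6 ± 0.709 CPM in activated Treg.

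Of the 21 lists 12 differed by camera. Adjusted p was 3.43e-07 for the Treg signature, 1.64e-06 for naive and quiescence, 2.98e-19 for helper effector, 0.000207 for follicular helper, 0.000207 for cell cycle, 0.000678 for homing receptors, 4.84e-13 for innate-like, 0.000106 for B cell and 2.65e-07 for myeloid genes. With an estimated correlation the helper effector and innate-like lists stayed past the threshold (0.0425 for both), and the others did not (adjusted p = 0.0924, 0.244, 0.112, 0.184, 0.218, 0.218 and 0.176 in that order). The inhibitory receptor list (0.0226) was lost without activated library 1 (0.0518). The cholesterol list (0.0344) was lost without naive library 1 (0.081), effector library 1 or 2 (0.0642 and 0.0654) or activated library 1 or 2 (0.059 and 0.0651). The interferon list (0.0251) was lost without naive library 2 (0.167), effector library 1 (0.129), resting library 1 (0.199) or activated library 2 (0.0651). With an estimated correlation these 3 lists had an adjusted p of 0.184, 0.184 and 0.527.

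Dendritic cell genes were high in effector Tconv: means in naive Tconv, effector Tconv, resting Treg and activated Treg were 2.58, 121, 9.47 and 46.9 CPM for Irf8 and 3.8, 409.8, 28.6 and 117 CPM for Cd74. A lower share of CD4 T cells with all other cell types alike is argued against by medians 3.63 apart. These were 6.38 for the first dendritic list and 2.75 for B cell genes (summed SE 1.32). For depth or scaling, the medians of the dendritic lists lay at least 6.37 above that of all other genes (summed SE 0.802). A factor per library moves all genes alike and could not make this gap, so the gap argues against depth or scaling as its source. It does not show whether scaling differed between libraries, since such a factor leaves any gap as it is. Both summed SEs are over genes, which are not independent. A candidate source is plasmacytoid dendritic cells, some of which carry CD4 and which the labels name no marker to remove: 100% of a second list (all 20 members tested, 5 of them at 1 CPM or more in naive Tconv and 1 in another list) were called higher in effector than in naive Tconv, against 61.4% of other genes of like naive abundance, a baseline set after the values were seen. All 12 conventional dendritic genes and all 11 tested plasma cell genes were also called higher in effector than in naive Tconv. A share of 100% therefore does not single out plasmacytoid cells. The rise was not particular to Tconv. In activated against resting Treg 13 of 13 genes of the first plasmacytoid list were called higher. In the second list 15 of 20 were higher and 2 lower, and 9 of 12 conventional dendritic genes were higher. From effector Tconv to activated Treg both plasmacytoid lists were lower by a like amount, with medians of -2.03 (MAD 0.457) and -2.09 (MAD 0.241). Conventional dendritic genes had a median of -2.27 (MAD 0.543), so other dendritic cells and expression in the T cells themselves stay open.

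Innate-like genes were also high in effector Tconv. Reads shared with other genes are argued against by a median log2 fold change of 6.34 over the 8 of 11 members with whole counts in all libraries, 7 of which were called higher. Gamma delta T cells as the whole source are argued against by Trdc, with a log2 fold change of -0.064 (SE 0.18, edgeR adjusted p = 0.814), where the median of Tcrg-C1, Tcrg-C2 and Tcrg-C4 was 8.63. Invariant NKT cells, some of which carry CD4, may contribute. Of the 3 alpha chain segments taken as markers of their receptor, Trav11 and Traj18 had 0 counts in every library. Trav11d had 483 and 425 counts in the effector libraries, 8 and 18 in the naive libraries, 3 and 9 in resting and 12 and 11 in activated Treg. The sum of the 3 therefore rests on Trav11d alone. The log2 ratio of effector to naive for the sum was 4.99, which is 5.81 above the median of 96 other Trav segments (-0.81, MAD 0.509), and 0 of these had a higher ratio. Expression of innate-like genes in other effector cells stays open.

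Ighm was higher in activated Treg than in the other populations (log2 fold change 1.87 against resting Treg and 1.53 against effector Tconv). B cells as the whole source are argued against by the other 13 B cell genes, whose median log2 fold change against resting Treg was 0.165 (MAD 0.980), although Ighd and Cd79b, singled out after their values were seen, rose with Ighm against resting Treg (1.79 and 0.83) and effector Tconv (1.80 and 1.60). Reads shared with another gene are argued against as well, since the expected count of Ighm, 7310 per library on average, was other than whole in 0 of 8 libraries. Plasma cells are argued against by their abundant genes Igkc and Jchain, at 8.59 and 3.56 CPM in resting and 10.7 and 4 CPM in activated Treg (log2 fold change plus 2 SE at most 0.886, and -1.09 against effector Tconv), although 5 of 11 plasma cell genes were higher than in resting Treg, with a median of 0.64 (MAD 1.54, camera adjusted p = 0.00708, and adjusted p = 0.222 with an estimated correlation). Transcription of the heavy chain constant region in activated Treg stays open as a hypothesis, untested and found on the same data.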

How the results depend on the processing

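Alternatives were planned except the run on protein-coding genes only, chosen after the data were seen. Over these, 70 of 79 counts of called genes stayed within 1.5 times the reported count. For effector against naive Tconv, activated against resting Treg, resting Treg against naive Tconv, activated Treg against effector Tconv and the difference, in that order, DESeq2 called 5193, 3339, 2501, 2469 and 1416 genes, limma-voom 6172, 4201, 2886, 3304 and 1560, and the run on protein-coding genes 5492, 3854, 2862, 3035 and 1487. With only the 4 libraries compared, 707 genes were lower in resting Treg than in naive Tconv, against 1132. With no filter the difference rose to 2274 genes, where more genes were tested. With 1 library left out the counts ran from 4473 to 7148, 2414 to 4273, 1636 to 3803, 2059 to 3796 and 982 to 1810. A group left with 1 library is then assumed to vary like the others, and the lowest counts came with a group of the comparison itself reduced to 1. No gene called both in a reported fit and under one of these settings changed sign there. Genes that lost their call were left out of this count. The median of all genes moved by less than 0.1 (log2), and the share of higher among called genes by less than 10 points.

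Of 8409 values for named genes, 8066 kept their direction and side of the threshold, 342 lost the threshold, 294 of these with 1 library left out and 25 under DESeq2, 1 passed it and 0 reversed. Of 696 values for lists called by camera, 635 held. An estimated correlation ended 41 of 58 calls, fry 3, and single omitted libraries 17 of their values, and the cause was not tested. The correlation of activation changes, 0.713, was 0.411 with no filter, 0.743 with the CPM filter and 0.746 on protein-coding genes, and 0.632 to 0.681 with 1 library left out. For lineage, 0.212 became 0.106 with no filter and 0.272 over genes called in either comparison, and 0.163 to 0.233 with 1 library left out. For both correlations the cause was not tested.

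With the replicate number as a block the counts were 7275, 5363, 4057, 4035 and 2130, of which 1707 were lower in resting Treg than in naive Tconv and 712 positive for the difference, and no call of a named gene or list was lost. The deviations of same-numbered libraries correlated at 0.046 to 0.138 over 6 pairs of groups, above 0.1 in 4. These values are low but all positive, and they neither show nor exclude that the numbers are a pairing. Small changes were often missed in the simulation with 2 libraries per group. For the difference between Treg and Tconv 11.9% of simulated 1.5-fold and 87.9% of 4-fold changes were recovered. Only 200 genes above 1 CPM were changed there, so these shares are not the power of the reported comparisons.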

Other observations

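The histone test was set before its result was seen. The ribosomal protein and oxidative phosphorylation genes were summarised after.

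Histone genes, whose replication-dependent members lack poly(A) tails and are captured in total RNA libraries, rose with CD44 in both lineages. In effector against naive Tconv 51 of 62 tested histone genes were higher and 1 lower by edgeR (camera adjusted p = 1.77e-11, and adjusted p = 0.0845 with an estimated correlation). In activated against resting Treg 42 of 62 were higher (camera adjusted p = 7.65e-14, and adjusted p = 0.142 with an estimated correlation). Hist1h1d, a linker histone gene, was at 38.1 and 37.5 CPM in the naive and 81.8 and 87.8 CPM in the effector libraries (log2 fold change 1.16, adjusted p = 3.55e-05), and at 38.5 and 35.3 CPM in the resting and 86.0 and 107.6 CPM in the activated Treg libraries (1.39, adjusted p = 3.26e-05). In activated Treg against effector Tconv 1 of 62 was called, lower. Hist1h1c, the most abundant of these genes, was not called in effector Tconv (-0.17, adjusted p = 0.548) or activated Treg (-0.072, adjusted p = 0.829). Many histone genes are near-identical copies, so single members are uncertain.

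Histone transcripts may follow the cell cycle genes in these populations. If so, most were to be called higher in both activation comparisons, and 66.1% were (41 of 62), against 13.8% of all tested genes. This is a hypothesis on the same libraries and does not separate more cycling cells from more histone RNA per cell.

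Ribosomal protein genes fell with activation in both lineages: 71 of 81 in effector Tconv (median log2 fold change -0.60, camera adjusted p = 1.59e-15, and adjusted p = 0.318 with an estimated correlation) and 73 of 81 in activated Treg (median -0.60, camera adjusted p = 1.91e-21, and adjusted p = 0.236 with an estimated correlation). Their change differed between lineages by a median of -0.0031 (MAD 0.149). Of 73 nuclear genes of oxidative phosphorylation, 9 rose in effector Tconv (camera adjusted p = 0.465) and 1 in activated Treg (0.0885). Of all 15563 tested genes, 3709 and 2716 were called higher in these comparisons. The gene that rose in activated Treg was Cox6a2 (log2 fold change 3.35, edgeR adjusted p = 0.00962), a member of the first plasmacytoid dendritic list. It also had the largest rise of the 73 in effector Tconv (6.30). Means of Cox6a2 were 0.0497, 4.19, 0.0588 and 0.717 CPM in naive Tconv, effector Tconv, resting Treg and activated Treg. Both CD44-low means lie below the CPM of 3 counts in a library. The fitted values 3.35 and 6.30 therefore rest on counts near 0 and are given without an interval. Of 13 mRNAs encoded in mitochondria, 1 fell in each of these comparisons (camera adjusted p = 0.342 and 0.0162, the latter 0.406 with an estimated correlation).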
